A study of Homo sapiens with 6 samples.

How the data were processed

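Total RNA of U2OS cells carrying GFP-DCP1A was sequenced in 6 libraries. Per the labels' protocols, ribosomal RNA was removed, the strand synthesis was followed by uridine digestion, a step that marks the strand, and the reads were sequenced on a HiSeq 2000. Per the submitters' processing notes, the tools were bcl2fastq, TopHat2, Bowtie2 and bedtools and the genome build was GRCh38 (hg38); versions, the gene annotation and the treatment of strand in counting are not given in the sources used here. The authors deposited raw counts per gene, 1 table per library, which are whole numbers with no normalization.

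Each table held 19940 gene rows with 19907 distinct names, of which 33 were on more than 1 row; repeated names were kept as separate rows and not named. All 19907 names were found among the protein-coding genes of GENCODE release 29, and 19874 had 1 location, which supplied the coordinates. What the counts include was inferred from the tables. The gene spans of RPS29, PTPRD and ANKRD28 enclose copies of the abundant 7SL RNA on the opposite strand, and RPS29 took 1.48% of the counts in the library labelled isotonic 1. The deposited counts thus appear to cover whole gene spans and both strands, so reads of overlapping and antisense genes may not be told apart. Exons and introns were not examined, and reads of 7SL were not separated from those of the genes themselves. These 3 rows took between 2.46% and 3.45% of the counts per library. Total counts per library ranged from 90196278 to 105991428, and counts limit precision for genes with few reads; intervals and floors of 3 counts cover counting error only.

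Samples were grouped by their titles into isotonic, hypertonic and rescue, and the groups were kept as labelled throughout. The grouping, the gene lists, the tests, the rule for named genes and the alternatives were fixed before the data were examined. All 6 libraries entered one edgeR quasi-likelihood model with a mean per group, after filterByExpr and TMM scaling, with robust dispersion, Benjamini-Hochberg adjustment and a two-sided threshold of 0.05. It tested 18208 genes, with a common dispersion of 0.148, a biological coefficient of variation of 38.4%, 3 residual degrees of freedom and a median prior of 1.49. CPM values are TMM-scaled, except where totals or families are described, and ± is the SD of 2 libraries. Ratios within a replicate number used TMM-scaled CPM plus 0.1, and those of all library pairs CPM without that scaling plus 0.1, over genes with at least 100 summed counts. Ratios within a number carry no test; only the fits that left out the isotonic and hypertonic library of the other number, with the spread taken from the rescue libraries, tested that difference.

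Named genes were the 8 largest rises and 8 largest falls of each comparison that passed the test with a mean of at least 5 CPM and no overlap between groups, up to 4 members per list that passed with a mean of at least 5 CPM, and a fixed set (DCP1A, NFAT5, SLC5A3, SLC6A6, AKR1B1, SLC38A2, HSPA1A, HSPA1B, FOS, EGR1, ATF3, CDKN1A, MYC and CPSF6). Since hypertonic against isotonic gave no calls, the largest ratios within number 1, overall and per list, were added after the values were seen. ATF3, of the fixed set, was at 13.1, 71.3, 67.5, 13.4, 98.7 and 96.1 CPM in the libraries labelled isotonic 1 and 2, hypertonic 1 and 2, and rescue 1 and 2.

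The lists covered osmoadaptive genes, heat shock, immediate early genes, p53 and ATF4 targets, endoplasmic reticulum chaperones, NF-kB, replication histones, ribosomal proteins, P-bodies, cleavage and polyadenylation, paraspeckles, cholesterol synthesis, S phase, G2 and mitosis, hypoxia, YAP targets, mitochondrially encoded genes, snoRNA hosts, bone lineage, and epithelial, leukocyte and endothelial markers, with zinc finger genes chosen by symbol. The 23 lists with measured members were tested with limma camera on voom values with a preset correlation of 0.01, adjusted over lists, beside an estimated correlation. The limma test fry was run on the same values and adjusted over lists. It asks whether the genes of a list changed, without comparing them with other genes. Percentiles came from 10000 random lists matched on mean expression. The neighbour sets, of genes close to a tested neighbour with a mean of at least 10 CPM, were tested the same way and adjusted over the pair of sets; this adjustment was added after the values were seen.

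The edgeR steps were tested on simulated data for rescue against isotonic over 18208 genes. At the spread within the labelled groups, 0% of genes changed 1.5-fold, 0% of those changed 2-fold and 22.7% of those changed 4-fold were recovered, with 3 false calls. At a spread of 0.002 all sizes were recovered at 100%, with 4 false calls. Each simulation changed only 66 or 67 genes per size and took all libraries as independent. The data held crossed pairs and far more calls, some of them under 2-fold. The recovered shares therefore do not describe the power of the fits to the data. Of 200 random lists of 25 genes, 2.5% had a camera p under 0.05.

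Alternatives were DESeq2 size factors, upper quartile scaling, no filter, a mean of at least 5 CPM, DESeq2, limma voom, a block on the replicate number, robust estimation off, only the 4 libraries compared, a 2-fold limit, other distances and levels for the neighbour sets, and each library left out in turn. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.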

Results

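The transcriptome of U2OS cells, a human osteosarcoma line, was measured by total RNA sequencing after removal of ribosomal RNA. The cells carried a stable transgene for GFP fused to DCP1A, a protein of the mRNA decapping complex that resides in P-bodies. The design text names 3 groups, with 2 libraries in each. In the isotonic group the medium held 150 mM sodium, in the hypertonic group 300 mM sodium for 4 h, and in the rescue group the hypertonic medium was followed by isotonic medium for 4 h. Rescue cells were thus harvested 4 h later than the others and after a further medium change. No isotonic group was kept for that time, so effects of the rescue and of the later harvest cannot be told apart. The stated purpose was to assess transcriptional changes. Total counts were 105336183 and 90196278 in the libraries labelled isotonic 1 and 2, 101403615 and 103529255 in those labelled hypertonic 1 and 2, and 105991428 and 91973726 in rescue 1 and 2. At these totals, 3 counts correspond to between 0.0283 and 0.0333 CPM, the counts scaled by the library total. The labels do not say that the libraries of a group came from separate cultures, and the protocol speaks of duplicate sequencing. P-values thus measure only the spread between these libraries, which may be technical in the rescue group. In isotonic and hypertonic the spread also held the large differences between number 1 and number 2 given below. It entered every comparison, since the groups shared one model.

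The libraries labelled isotonic and hypertonic did not group by their labels. Between isotonic 1 and isotonic 2 the SD of the log2 ratio across 15634 genes was 0.946, and 3424 genes differed by 2-fold or more. Between hypertonic 1 and hypertonic 2 the SD was 0.942, with 3443 such genes. By contrast, isotonic 1 and hypertonic 2 differed with an SD of 0.126 and 10 genes at 2-fold, and isotonic 2 and hypertonic 1 with an SD of 0.136 and 6 genes. The rescue libraries differed from each other with an SD of 0.149 and 9 genes. Repeat sequencing of one library would differ by read sampling alone, with a mean chi-square per gene near 1. The values were 5.92 for isotonic 1 with hypertonic 2 and 10.55 for rescue 1 with rescue 2, which does not show that the libraries came from separate cultures. All 6 libraries were kept as separate samples under their labels, and each direction below refers to the library labelled with that condition.

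DCP1A, on chromosome 3 from 53283428 to 53347610 (GRCh38), was measured at 940 and 885 CPM in the libraries labelled isotonic 1 and 2, at 863 and 934 CPM in those labelled hypertonic 1 and 2, and at 461 and 438 CPM in rescue 1 and 2. These counts include any reads from the transgene that match the gene.

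The comparison of the hypertonic with the isotonic group asks what the osmotic change did to transcript levels, and its answer differed in direction between the replicate numbers. In number 1, genes of osmotic adaptation were higher in the library labelled hypertonic. SLC38A2, an amino acid transporter, stood at 3048 CPM in hypertonic 1 and 346 CPM in isotonic 1. The inositol transporter SLC5A3 stood at 789 and 170 CPM, the taurine transporter SLC6A6 at 415 and 109 CPM, the aldose reductase gene AKR1B1 at 190 and 67.4 CPM, and NFAT5, the transcription factor of the hypertonic response, at 486 and 160 CPM. In number 2 the same genes were lower in the library labelled hypertonic: SLC38A2 stood at 351 CPM in hypertonic 2 and 3072 CPM in isotonic 2, and NFAT5 at 167 and 515 CPM. The rows of SLC5A3 and MRPS6 overlap in the annotation, so the value of SLC5A3 is uncertain.

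**Figure D1:**
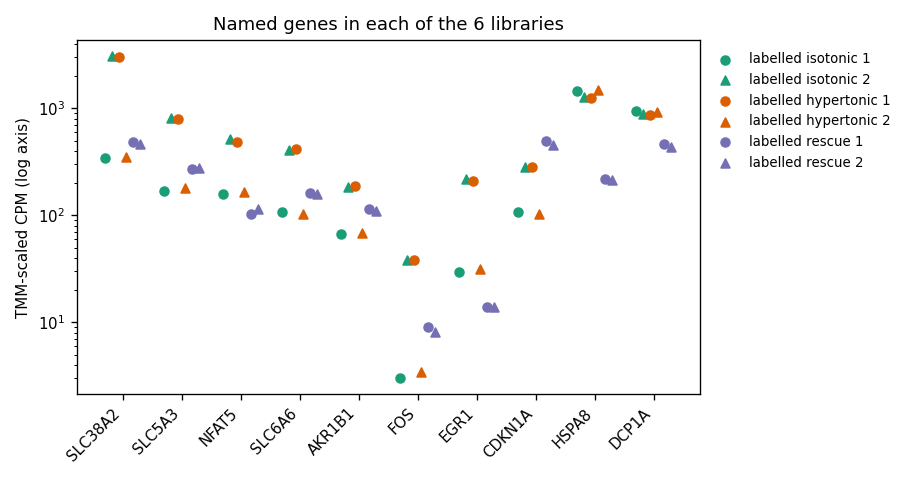
TMM-scaled CPM on a log axis for 10 named genes in each of the 6 libraries, with color for the labelled group and the marker shape for the replicate number. For SLC38A2, the libraries labelled isotonic 2 and hypertonic 1 lie at 3072 and 3048 CPM, and those labelled isotonic 1 and hypertonic 2 at 346 and 351 CPM.

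Across the osmoadaptive list of 16 measured genes, the median log2 ratio of hypertonic over isotonic was 1.67 in number 1 and -1.65 in number 2. In number 1, 11 of the 16 were higher by at least 2-fold and 1 was lower; in number 2, 10 were lower and 0 were higher. These medians lay at percentiles 100 and 0 of 10000 random lists of the same size matched on mean expression. A ratio of 1 library over 1 library has no replicate check, and the percentiles describe these libraries only.

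Immediate early genes moved alongside. Their median log2 ratio over 36 genes was 1.86 in number 1 and -1.90 in number 2, with 24 genes higher by at least 2-fold in the first and 24 lower in the second. FOS was measured at 38.2 CPM in hypertonic 1 against 3.02 CPM in isotonic 1, FOSB at 172.5 against 1.38 CPM, and EGR1 at 209 against 29.7 CPM. In number 2 FOS was measured at 3.41 CPM in hypertonic 2 against 38.5 CPM in isotonic 2. The row of FOSB overlaps that of ERCC1. Hypoxia and glycolysis genes had medians of 0.63 in number 1 and -0.65 in number 2, where VEGFA, the vascular growth factor, stood at 99.3 CPM in hypertonic 1 and 27.9 CPM in isotonic 1. Targets of YAP, a growth regulator, had medians of 0.58 and -0.63.

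Other lists were lower in hypertonic 1 and higher in hypertonic 2. The NF-kB list had medians of -1.11 and 0.90 over 19 genes, and its members went both ways: in number 1, 10 were lower by at least 2-fold and 6 were higher. BIRC3, an inhibitor of apoptosis, was at 13.8 CPM in hypertonic 1 and 147.3 CPM in isotonic 1, while TNFAIP3, a feedback inhibitor of the pathway, was at 138.6 and 23.7 CPM. Replication histone genes had medians of -0.65 and 0.68, with 13 of 49 lower by at least 2-fold in number 1 and 0 higher. Genes of G2 and mitosis had medians of -0.51 and 0.48. Zinc finger genes with ZNF symbols, many of them transcriptional repressors, had medians of -0.66 and 0.66, with 156 of 465 lower and 13 higher by at least 2-fold in number 1. Histone and zinc finger genes have near-identical relatives, so their single values are uncertain.

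The largest ratios within number 1, by a rule added after the values were seen, were those of CALB1 (55.9 CPM in hypertonic 1 and 0.18 CPM in isotonic 1), THEMIS (22.2 and 0.02 CPM), AGR2 (23.3 and 0.10 CPM) and FOSB, and in the other direction those of TRAF1 (2.28 and 90.4 CPM) and ZNF662 (1.43 and 20.8 CPM). The row of ZNF662 overlaps that of KRBOX1. The same genes stood at 0.23 CPM (CALB1) and 87.3 CPM (TRAF1) in hypertonic 2, and at 54.4 and 2.40 CPM in isotonic 2.

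Over 13155 genes with a mean of at least 5 CPM, 992 were higher and 1266 lower by at least 2-fold in hypertonic 1 than in isotonic 1, and 1223 were higher and 1003 lower in hypertonic 2 than in isotonic 2. Of the 2047 genes that differed by at least 2-fold in both numbers, 2046 did so in opposite directions. Across genes, which are not independent replicates, the ratios of number 1 and number 2 had a Pearson r of -0.988 and a Spearman rho of -0.984.

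**Figure D2:**
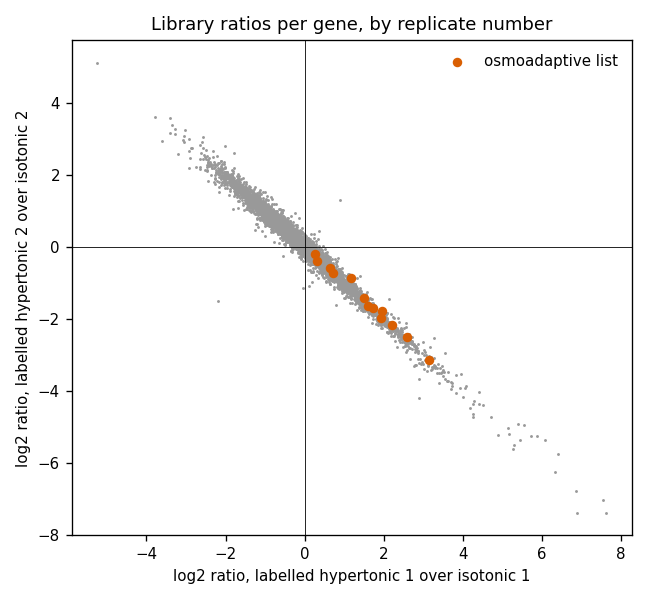
Each point is a gene with a mean of at least 5 CPM; the x axis gives the log2 ratio of the library labelled hypertonic 1 over isotonic 1 and the y axis that of hypertonic 2 over isotonic 2. The points fall along a line of negative slope (Pearson r of -0.988), and 11 of the 16 osmoadaptive genes were at least 2-fold higher in number 1.

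With the libraries grouped as labelled, no gene passed the test between hypertonic and isotonic. Of 18208 genes tested with the edgeR quasi-likelihood test and Benjamini-Hochberg adjustment, 0 were higher and 0 lower at an adjusted p of 0.05, and 52 had an unadjusted p under 0.05. DESeq2 called 1 gene lower, the sulfotransferase gene SULT1C2 (log2 fold change -2.22, SE 0.347, adjusted p = 2.81e-06), and limma voom called 0, with 42 and 44 genes at an unadjusted p under 0.05. The smallest adjusted p of the edgeR quasi-likelihood test was 1. Of the 23 lists tested, none passed by limma camera, with a smallest Benjamini-Hochberg adjusted p of 0.626. In every list 0 members passed, over all genes and adjusted over the list alone. With the 4 libraries blocked on the crossed pairs (isotonic 1 with hypertonic 2, isotonic 2 with hypertonic 1), a setting chosen after seeing the data, 6 genes were higher and 15 lower. The counts of 0 rest on a within-group spread that includes the differences between number 1 and number 2. With the libraries labelled isotonic 2 and hypertonic 2 left out, a setting chosen after seeing the data, the same test called 5828 genes higher and 6013 lower (the number 1 fit), and with isotonic 1 and hypertonic 1 left out it called 6060 higher and 5716 lower (the number 2 fit). Of the 10673 genes called in both of these fits, 10665 had opposite directions. Each lone library was assumed to vary like the rescue libraries.

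Hyperosmotic stress is known to impair transcription termination, so genes close behind an expressed neighbour were compared with all others. One set held 2315 genes with an expressed neighbour ending within 10 kb upstream on the same strand, and another 2413 genes facing an expressed neighbour tail to tail within 10 kb. With the libraries grouped as labelled, neither set passed in hypertonic against isotonic, with medians above those of other genes by 0.01 and 0.005 on the log2 scale. For both sets limma camera gave a Benjamini-Hochberg adjusted p = 0.456, over the pair of sets. Per number, tail-to-tail genes had a median log2 ratio of 0.054 in number 1 against -0.006 for other genes, and of -0.041 against 0.006 in number 2, so the grouped value averages opposite shifts. These medians lay at percentiles 100 and 0 of 2000 random lists. Genes behind a same-strand neighbour had medians of -0.001 and 0.027, at percentiles 95.9 and 30.2.

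The comparison of the rescue with the isotonic group asks how far transcript levels stood from the isotonic state 4 h after the return to isotonic medium. By single genes, 17 of 26 genes of G2 and mitosis, 12 of 26 of S phase, 10 of 22 of the heat shock list and 9 of 21 of cholesterol synthesis were lower in rescue, and 11 of 24 p53 targets were higher. As lists none of these passed limma camera with an estimated correlation (adjusted p = 0.41, 0.252, 0.252, 0.348 and 0.252). By fry, which does not compare a list with other genes, all of them passed (adjusted p = 0.0156, 0.00207, 0.0037, 0.0111 and 0.00343). HSPA8, the constitutive cytosolic HSP70 chaperone on chromosome 11 from 123057489 to 123063230, was measured at 216 ± 3.59 CPM in rescue and 1367 ± 136 CPM in isotonic (mean ± SD, n = 2 each), a 6.34-fold lower level (edgeR quasi-likelihood test, adjusted p = 0.00834). MEX3A, an RNA-binding protein gene, was 6.77-fold lower and CCNE1, the gene of cyclin E1, was at 17.4 and 17.2 CPM in rescue against 64.0 and 116 CPM in isotonic. KYNU, the kynureninase gene, was at 50.2 ± 2.74 CPM in rescue and 0.31 ± 0.044 CPM in isotonic, 163-fold higher (edgeR quasi-likelihood test, adjusted p = 0.00834).

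Other genes with the largest rise were MS4A4A (111-fold), CYP4F2 (95.3-fold), the monocarboxylate transporter gene SLC16A6 (88.2-fold), and the transcriptional coactivator gene EYA4 (60.6-fold), each under 1 CPM in all isotonic libraries. SERPINB3 and SERPINB11, which overlap each other, were at 12.6 to 15.1 CPM in the rescue libraries and under 1 CPM in the isotonic ones. CYP4F3 was at 12.4 ± 0.571 CPM in rescue and 0.222 ± 0.287 CPM in isotonic (mean ± SD, n = 2 each). CYP4F2 and CYP4F3 are close relatives, SERPINB3 has a near-identical neighbour, the row of MS4A4A overlaps that of MS4A4E and the row of SLC16A6 that of ARSG, so these values are uncertain. In the same rescue libraries fewer genes had no count, 690 and 699 against 1248 to 1653 in the other libraries, and 386 olfactory receptor genes summed to 116 and 125 CPM, unscaled, against 41.0 to 61.1 CPM. Among the largest falls were BEND7, KIAA1147, CCNJL, the hairless corepressor gene HR (5.06-fold) and RASL10B (4.87-fold), which overlaps TAF15. DCP1A fell by 1.02 on the log2 scale (SE 0.098; edgeR quasi-likelihood test, adjusted p = 0.0094).

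Of 26 genes of G2 and mitosis, 17 were lower in rescue, 20 when adjusted over the list alone, and 0 were higher. The survivin gene BIRC5 was 3.22-fold lower, the spindle factor gene TPX2 3.23-fold and the kinesin gene KIF11 3.02-fold, and BUB1B, of the spindle checkpoint, was at 24.0 and 24.6 CPM against 110 and 72.1 CPM. The row of BUB1B overlaps a readthrough row. The list was lower by limma camera (adjusted p = 5.54e-08), but with an estimated correlation the adjusted p = 0.41. Of 26 S phase genes, 12 were lower, 13 when adjusted over the list alone, among them CCNE1, the ribonucleotide reductase gene RRM2 (3.44-fold) and UHRF1 (limma camera, adjusted p = 8.45e-06; adjusted p = 0.252 with an estimated correlation). Replication histone genes were mixed, with 11 of 49 lower and 5 higher, and 14 lower and 5 higher when adjusted over the list alone (limma camera, adjusted p = 0.00423; adjusted p = 0.727 with an estimated correlation). HIST1H2BJ was 3.85-fold lower and HIST1H2BE 5.79-fold higher, both uncertain for their near-identical relatives. With upper quartile scaling 7 were lower and 5 higher. The median of the list was -0.89, and -1.02 and -0.40 in the number 1 and number 2 fits.

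Of 24 p53 targets, 11 were higher, 15 when adjusted over the list alone, and 0 were lower (1 lower over the list alone). The stress cytokine gene GDF15 was 36.4-fold higher, the antiproliferative gene BTG2 8.95-fold, SESN1 5.81-fold and the death receptor gene FAS 5.77-fold (limma camera for the list, adjusted p = 2.27e-06; adjusted p = 0.252 with an estimated correlation). The row of FAS overlaps that of ACTA2. CDKN1A, the p53-induced cell cycle inhibitor, did not pass: it was at 492 and 456 CPM in rescue and at 107 and 283 CPM in isotonic (edgeR quasi-likelihood test, adjusted p = 0.245).

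Among 22 chaperones of the heat shock list, 10 were lower and 1 was higher, and 11 and 1 when adjusted over the list alone. Besides HSPA8, HSPD1 was 2.45-fold lower, and HSPE1 and CHORDC1 were lower (limma camera, adjusted p = 0.000264; adjusted p = 0.252 with an estimated correlation). HSPD1 and HSPE1 are neighbours with overlapping rows. Of the near-identical pair HSPA1A and HSPA1B, HSPA1A was at 156 and 151 CPM in rescue against 226 and 265 CPM, and HSPA1B did not pass. Of 18 endoplasmic reticulum chaperones 5 were lower, 7 when adjusted over the list alone, such as SEL1L and HYOU1 (limma camera, adjusted p = 0.00169; adjusted p = 0.348 with an estimated correlation). With upper quartile scaling 0 of the 18 passed. Of 21 cholesterol genes 9 were lower, 11 when adjusted over the list alone, with SQLE, the squalene epoxidase gene, at 59.9 ± 1.78 CPM in rescue and 195 ± 59.9 CPM in isotonic, and DHCR7 and MSMO1 lower (limma camera, adjusted p = 3.95e-05; adjusted p = 0.348 with an estimated correlation).

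Of 26 factors of 3' end cleavage and polyadenylation 10 were lower, and 10 when adjusted over the list alone, including CPSF2 (2.32-fold) and CPSF3 (limma camera, adjusted p = 0.00136; adjusted p = 0.252 with an estimated correlation). CPSF6, a subunit of the cleavage factor, was 1.67-fold lower (edgeR quasi-likelihood test, adjusted p = 0.0471). Of 28 P-body and deadenylation genes 10 were lower and 1 was higher, and 14 and 1 when adjusted over the list alone. With upper quartile scaling 5 were lower and 2 higher. DCP1A is one of them; EDC4, a decapping scaffold, and CNOT1, the deadenylase scaffold, were lower, and TNRC6C, an Argonaute partner, was 2.26-fold higher (limma camera, adjusted p = 0.00325; adjusted p = 0.252 with an estimated correlation). Of 7 paraspeckle genes 3 were lower, and 3 when adjusted over the list alone, with NONO, an RNA-binding protein gene, among them (limma camera, adjusted p = 0.0211; adjusted p = 0.452 with an estimated correlation). The median of that list was -0.74, and -0.46 and -0.76 in the number 1 and number 2 fits.

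Of 465 zinc finger genes 47 were higher and 16 lower, and 30 and 12 when adjusted over the list alone, with a median log2 fold change of 0.70 (limma camera, adjusted p = 2.14e-06; adjusted p = 0.649 with an estimated correlation). With upper quartile scaling 61 were higher and 10 lower. The median was 0.39 in the number 1 fit and 1.20 in the number 2 fit. ZNF844 was 8.66-fold higher and ZNF442 14.9-fold. The osmoadaptive list did not pass (limma camera, adjusted p = 0.626). Over the 2 isotonic libraries it had a median of -0.68, with 1 of 16 genes higher and 1 lower, over all genes and adjusted over the list alone. Its median log2 fold change was 0.50 in the number 1 fit and -0.89 in the number 2 fit, so its direction turned with the isotonic library used, and with upper quartile scaling 0 were lower. NFAT5 was at 103 and 115 CPM in rescue against 160 and 515 CPM in isotonic, and SLC38A2 at 482 and 466 CPM against 346 and 3072 CPM. Immediate early genes did not pass as a list (limma camera, adjusted p = 0.823), with 2 of 36 higher and 1 lower, and the same counts when adjusted over the list alone. The median of the list was -0.52 while the direction of the test was up, and in the number 1 and number 2 fits the median was 0.85 and -1.15. MYC was lower, at 42.3 and 39.3 CPM in rescue against 127 and 199 CPM, and BTG2, which is also among the p53 targets, and RHOB were higher.

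Of the remaining lists, ATF4 targets had 5 of 23 higher and 5 lower (5 and 2 with upper quartile scaling), and 7 and 6 when adjusted over the list alone (limma camera, adjusted p = 0.626). DDIT3 was higher and MTHFD2 lower, and both overlap other genes. YAP targets had 1 of 16 higher and 4 lower, 2 lower with upper quartile scaling, with THBS1, which overlaps FSIP1, 3.32-fold lower, and 1 and 5 when adjusted over the list alone (limma camera, adjusted p = 0.204). The NF-kB list had 1 of 19 lower, LIF, over all genes and adjusted over the list alone (limma camera up, fry down, adjusted p = 0.708 by camera). The hypoxia list had 1 of 21 lower, ENO2, which overlaps LRRC23, and 0 when adjusted over the list alone (limma camera, adjusted p = 0.646). Ribosomal protein genes had 1 of 79 lower, RPL34, and 0 when adjusted over the list alone (limma camera, adjusted p = 0.0174; adjusted p = 0.818 with an estimated correlation); their median log2 fold change was -0.12, and 0.10 with upper quartile scaling. Of 13 mitochondrially encoded genes 0 passed, over all genes and adjusted over the list alone (limma camera, adjusted p = 0.0697). Of 16 bone lineage genes LOX was lower, and 0 passed when adjusted over the list alone (limma camera, adjusted p = 0.189). Long noncoding snoRNA host genes had 0 measured members. With upper quartile scaling the single calls of the hypoxia, ribosomal protein and bone lineage lists were lost. For YAP and hypoxia the direction turned with the isotonic library used. The YAP median was -0.26, and 0.11 and -0.55 in the number 1 and number 2 fits, with 7 higher and 7 lower in the first and 2 and 13 in the second. The hypoxia median was -0.13 (0.09 with upper quartile scaling), and 0.17 and -0.45 in these fits. The medians of other lists in the number 1 and number 2 fits were 0.37 and 0.17 for ATF4, 0.17 and 0.94 for NF-kB, -0.01 and -0.22 for ribosomal proteins, and -0.16 and -0.29 for bone lineage.

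Of markers of other cell types, 3 of 12 epithelial, 1 of 9 leukocyte and 3 of 10 endothelial markers were higher in rescue, with 4, 1 and 4 when adjusted over the list alone (limma camera, adjusted p = 0.0586, 0.0641 and 0.0377; adjusted p = 0.407, 0.359 and 0.452 with an estimated correlation). EPCAM, an epithelial marker, was at 10.6 ± 0.622 CPM in rescue against 4.05 ± 0.696 CPM in isotonic (mean ± SD, n = 2 each). In the same rescue libraries 690 and 699 genes had no count against 1248 to 1653 in the other libraries. The medians of the epithelial, leukocyte and endothelial lists were 0.90, 1.87 and 1.29 in the number 1 fit and 1.12, 0.80 and 1.13 in the number 2 fit, against 0.60, 0.57 and 1.11.

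**Figure D3:**
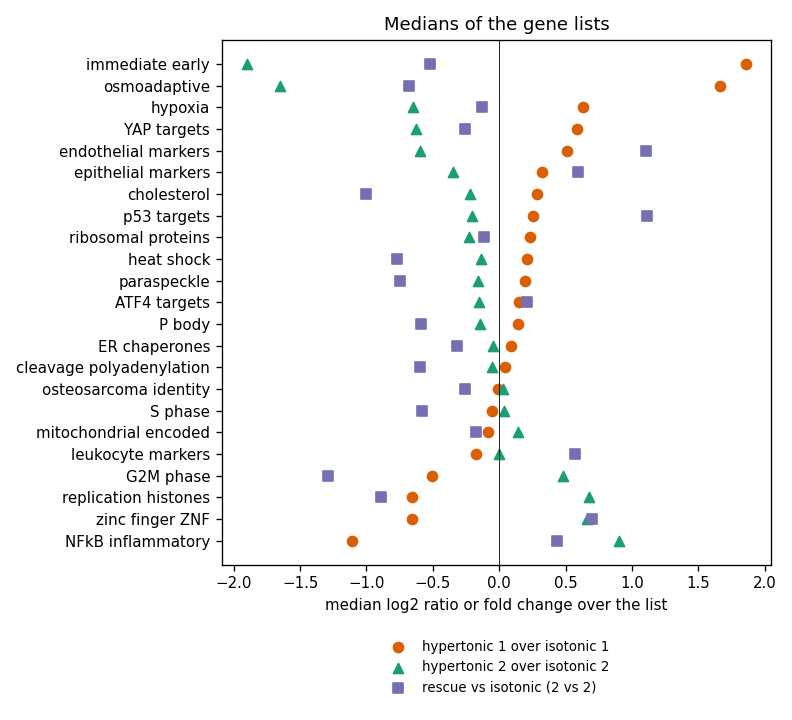
Medians of each gene list on the log2 scale: the ratio of hypertonic 1 over isotonic 1, that of hypertonic 2 over isotonic 2, and the fold change of rescue against isotonic with 2 libraries in each group. The osmoadaptive list lies at 1.67 and -1.65 in the 2 numbers, and the G2 and mitosis list at -1.29 in rescue against isotonic.

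In all, 1749 of 18208 genes were higher and 2453 lower in rescue than in isotonic by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, of which 1515 and 935 differed by at least 2-fold. The spread behind these calls held the differences between number 1 and number 2 of isotonic and hypertonic. A gene that differed much between the numbers was less likely to pass. Few calls in a list therefore do not show that the list was unchanged. The number 1 and number 2 fits took their spread from the rescue libraries alone. That they kept these calls, as given below, is therefore no separate check of them. Leaving out isotonic 1, isotonic 2, rescue 1 or rescue 2 alone left 0 calls each with 3652 to 6572 genes at an unadjusted p under 0.05, and so did a block on the replicate number, with 4896, whereas the number 1 and number 2 fits, with 1 isotonic library each, kept 4201 of the 4202 calls each. Upper quartile scaling moved the median of all genes from -0.02 to 0.19 and the share of higher calls from 41.6% to 59.8%, while DESeq2 called 3280 genes higher and 3761 lower, mean CPM of at least 5 left 1108 and 1523, and the fits without isotonic 2 and hypertonic 2 or without isotonic 1 and hypertonic 1 called 7476 and 7115 or 7496 and 7402.

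The comparison of the rescue with the hypertonic group spans the return to isotonic medium together with the later harvest. It named largely the genes of the preceding comparison. KYNU, CYP4F2, MS4A4A, SULT1C2, SLC16A6, CYP4F3, EYA4 and FAM9B had the largest rises, and MEX3A, HSPA8, BEND7, HR, KIAA1147, CCNE1, CCNJL and RASL10B the largest falls. HSPA8 fell by 2.66 on the log2 scale (SE 0.14; edgeR quasi-likelihood test, adjusted p = 0.00832). DCP1A fell by 1.00 (SE 0.098; edgeR quasi-likelihood test, adjusted p = 0.00953). NFAT5 was at 103 and 115 CPM in rescue against 486 and 167 CPM in the libraries labelled hypertonic 1 and 2, and did not pass (edgeR quasi-likelihood test, adjusted p = 0.208).

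Of the fixed lists, 17 of 26 genes of G2 and mitosis, 12 of 26 of S phase, 10 of 21 of cholesterol synthesis, 10 of 26 of cleavage and polyadenylation and 11 of 28 of P-bodies were lower, against 0, 0, 0, 0 and 1 higher (5 of P-bodies lower with upper quartile scaling). Adjusted over the list alone, 20, 12, 11, 10 and 14 were lower. The limma camera adjusted p values were 7.29e-08, 1.12e-05, 3.11e-05, 0.00115 and 0.00304. With an estimated correlation they were adjusted p = 0.431, 0.251, 0.342, 0.251 and 0.251. Of 24 p53 targets 11 were higher, 14 when adjusted over the list alone, and 0 were lower, 1 over the list alone (limma camera, adjusted p = 3.67e-06; adjusted p = 0.251 with an estimated correlation). The osmoadaptive list had 1 of 16 higher and 1 lower, over all genes and adjusted over the list alone (limma camera, adjusted p = 0.576), with a median of -0.93 in the number 1 fit and 0.51 in the number 2 fit. In these fits the direction also turned for immediate early genes (-1.12 and 0.84), hypoxia (-0.36 and 0.23), YAP targets (-0.50 and 0.12) and ribosomal proteins (-0.24 and 0.02). The median of genes behind a same-strand expressed neighbour, less that of other genes, was -0.28 on the log2 scale (limma camera, adjusted p = 0.0053; adjusted p = 0.0785 with an estimated correlation). Against isotonic it was -0.26 (limma camera, adjusted p = 0.00714; adjusted p = 0.0838 with an estimated correlation). For tail-to-tail genes these differences were -0.26 and -0.26 (limma camera, adjusted p = 0.012 and 0.0139; adjusted p = 0.0785 and 0.0838 with an estimated correlation). In no comparison did a list pass limma camera with an estimated correlation. By fry, rescue against isotonic, cleavage and polyadenylation, P-bodies, endoplasmic reticulum chaperones and paraspeckles passed too (adjusted p = 0.000745, 0.0037, 0.0117 and 0.0261). So did bone lineage, mitochondrially encoded genes and the epithelial, leukocyte and endothelial markers (fry, adjusted p = 0.0114, 0.0281, 0.0196, 0.00564 and 0.0283). The remaining lists did not (fry, adjusted p of at least 0.132).

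In all, 1796 of 18208 genes were higher and 2508 lower in rescue than in hypertonic by the edgeR quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, of which 1552 and 954 differed by at least 2-fold. Here too the number 1 and number 2 fits took their spread from the rescue libraries alone, so the calls they kept are no separate check. The limit on the spread given for rescue against isotonic holds for the main test here as well. Leaving out hypertonic 1, hypertonic 2, rescue 1 or rescue 2 left 0 calls each with 3675 to 6631 genes at an unadjusted p under 0.05, as did the block with 4984, while the number 1 and number 2 fits kept 4303 of 4304 each, and upper quartile scaling moved the share of higher calls from 41.7% to 59.6%. DESeq2 called 3317 and 3788 genes, mean CPM of at least 5 left 1135 and 1545, and the fits without the isotonic and hypertonic libraries of number 2 or of number 1 called 7561 and 7466 or 7475 and 7111.

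Of the genes called in both rescue comparisons, 1621 were higher and 2404 lower in rescue in both, and 0 had opposite directions. Lists drawn independently would share 173 and 338, and 20 simulations of unchanged groups, which share the rescue libraries, gave 0 and 0. The fold changes had a Pearson r of 0.952 across genes and a covariance of 1.747, against 0.493 and 0.232 in the simulations. The simulations took all libraries as independent, which the crossed pairs were not, so they give no reference for these values. The isotonic and hypertonic groups as labelled had nearly equal means, since each held a library of either kind, so both comparisons set the rescue libraries against nearly the same values and are not independent of each other.

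The fold changes of hypertonic against isotonic and of rescue against isotonic had a Pearson r of 0.168 across genes, a Spearman rho of 0 and a covariance of 0.095. The simulations gave 0.504, 0.462 and 0.238 for unchanged groups that share the isotonic libraries. These simulations took all libraries as independent, whereas the differences between numbers 1 and 2 correlated at -0.905 between isotonic and hypertonic across genes, so they give no reference for the observed values. The calls of these comparisons overlapped at 0 genes and reversed at 0 genes, since the first had none. Without hypertonic 2 the r was -0.042, without isotonic 2 it was 0.584, without isotonic 1 0.524 and without hypertonic 1 0.062.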

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

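The tests of label exchange and depth in this part were chosen after the crossing was seen, as was the comparison of directions between the replicate numbers. For these lists the difference between numbers was not tested; by single genes, 10673 were called in both the number 1 and the number 2 fit, 10665 of them in opposite directions.

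Several fixed lists moved one way from isotonic to hypertonic in number 1 and the other way in number 2, outside the middle 95% of random lists in both. As median log2 ratios in number 1 and number 2, these were 1.666 and -1.653 for osmoadaptive genes, 1.862 and -1.902 for immediate early genes, 0.628 and -0.653 for hypoxia, and 0.584 and -0.627 for YAP targets. In the other direction they were -1.11 and 0.902 for NF-kB, -0.654 and 0.678 for replication histones, -0.51 and 0.479 for G2 and mitosis, -0.657 and 0.658 for zinc finger genes, and -0.081 and 0.14 for mitochondrially encoded genes. Genes tail to tail with an expressed neighbour had 0.054 and -0.041, by the same limits. Across genes the ratios of the 2 numbers had a Pearson r of -0.988. A list far out in number 1 thus tends to lie far out the other way in number 2. These items restate the crossed pairing, and number 2 is no separate check of number 1.

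The libraries labelled isotonic and hypertonic paired across their labels. Depth is argued against: thinned to one depth, the smaller SD of log2 ratios within a label was still 0.825, against at most 0.097 across labels. An exchange of isotonic 1 with hypertonic 1 is argued against by the osmoadaptive median of 1.666 in number 1, since it would put genes of the hypertonic response low in hypertonic cells. An exchange of isotonic 2 with hypertonic 2 is a candidate explanation that stays open. The larger SD across labels was 0.116 of the smaller SD within a label. This ratio restates the pairing that raised the explanation and adds no support. The osmoadaptive median of -1.653 in number 2 put genes of the hypertonic response low in the library labelled hypertonic 2. Such an exchange would give that value, but given the pairing it mirrors the value in number 1. An exchange and another cause shared by the crossed pairs therefore cannot be told apart. Of the 3 ways to part the 4 libraries 2 against 2, the labels gave 0 calls, the numbers 0, and isotonic 1 with hypertonic 2 against the other pair 13916; that split points to a structure of the samples but was likewise drawn from the pairing already seen, and 3 splits are too few for a share under 0.05.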

How the results depend on the processing

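The fits without the isotonic and hypertonic libraries of one number and the block on crossed pairs were chosen after seeing the data. For hypertonic against isotonic, the 0 calls in each direction held under the alternatives fixed beforehand except DESeq2, with 1 gene lower. Without isotonic 2 and hypertonic 2, 5828 genes were higher and 6013 lower, and without isotonic 1 and hypertonic 1, 6060 and 5716, with the spread taken from the rescue pair alone; leaving out 1 library gave 0, and the cause was not tested. The replicate numbers did not pair the samples (correlation of deviations -0.905 between isotonic and hypertonic, -0.025 and 0.038 with rescue). With a block on the crossed pairs (isotonic 1 with hypertonic 2, isotonic 2 with hypertonic 1), hypertonic against isotonic gave 6 genes higher and 15 lower. The replicate block gave 0 genes higher and 0 lower in each of the 3 comparisons.

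For rescue against hypertonic, higher and lower calls were 1135 and 1545 at a mean of at least 5 CPM, where fewer genes were tested, 3317 and 3788 by DESeq2, 7561 and 7466 without isotonic 2 and hypertonic 2, and 7475 and 7111 without isotonic 1 and hypertonic 1. Lower calls were 1448 with upper quartile scaling and 954 at 2-fold. Leaving out 1 library gave 0 to 1681 higher and 0 to 2017 lower. For rescue against isotonic the same settings gave 1108 and 1523, 3280 and 3761, 7476 and 7115, and 7496 and 7402, with 1404 and 935 lower, and 0 to 1541 higher and 0 to 1920 lower on leaving out 1 library. Of the 4202 calls, upper quartile scaling kept 3143 and DESeq2 4187, and 0 calls of either rescue comparison changed sign under the alternatives run. Of 158 named gene calls, upper quartile scaling ended 28, and leaving out either rescue library ended 158; the cause was not tested. The correlation of hypertonic and rescue fold changes was -0.039 at a mean of at least 5 CPM and -0.042 to 0.584 on leaving out 1 library. In hypertonic against isotonic, the neighbour sets gave camera p from 0.193 to 0.951 under the alternatives run, and the tail-to-tail difference turned to -0.0145 without isotonic 1 and -0.0287 without hypertonic 1. The tables of pseudocounts and low values were not run, since the values are counts. In the simulations of rescue against isotonic, depth was not the limit for genes of at least 5 CPM. At the same depth, all simulated changes were recovered at a spread of 0.002. For hypertonic against isotonic this was not simulated. There the common dispersion was 0.148 as labelled. At the same depth it was 0.00115 with the libraries parted by the crossed pairs, a split drawn from the pairing already seen.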

Other observations

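The genes named in this part outside the lists were chosen after their values were seen, as were the test of depth and that of medians near and far from expressed genes. The other tests of genomic DNA, run-on transcription, gene span, abundance and the chromosome 19 cluster were set before they were run. The cluster itself was drawn from the named genes.

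TXNIP, a glucose-responsive inhibitor of thioredoxin, was at 11.8, 5.45, 5.57 and 12.6 CPM in the libraries labelled isotonic 1, isotonic 2, hypertonic 1 and hypertonic 2, and at 372 and 354 CPM in rescue 1 and 2. Its relative ARRDC4, induced by the same glucose-sensing factors, was at 5.71 and 5.00 CPM in the libraries labelled isotonic 1 and 2 and was 4.41 higher on the log2 scale in rescue (SE 0.253; edgeR quasi-likelihood test, adjusted p = 0.00834).

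The zinc finger genes that the naming rule picked, ZNF844, ZNF433, ZNF442 and ZNF44, lie in one cluster on chromosome 19 between 11559374 and 12551542 (GRCh38). Of 22 zinc finger genes tested there, 21 had a fold change above 0 in rescue against isotonic and 8 passed the edgeR quasi-likelihood test, with 0 lower. Their median log2 fold change was 2.12, against 0.67 for the 443 zinc finger genes outside. The cluster was picked for holding the genes named by size of change, and its median includes them, so this contrast is no independent result. The cluster median of hypertonic over isotonic was -0.74 in number 1 and 0.82 in number 2. Random lists of 2000 draws ask whether other genes of like span or abundance shifted as much; they ignore correlation between genes and do not replace the list call, which is lost with an estimated correlation (limma camera, adjusted p = 0.649). Genes matched on span had a mean median of -0.04 and those matched on mean CPM 0.03, against 0.70 (percentiles 100.0 and 100.0), which argues against a trend with span or abundance as the whole difference. Without the cluster the median was still 0.67 (percentile 100.0), which argues against run-on or shared reads within it as the whole cause. Shared reads among zinc finger genes elsewhere stay open, as does a difference brought by the rescue or by its later harvest.

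Fewer genes had no count in the rescue libraries: 690 and 699, against 1627, 1270, 1248 and 1653 in isotonic 1 and 2 and hypertonic 1 and 2. Olfactory receptor genes, silent in most cells, summed to 116 and 125 CPM in rescue and 41.0 to 61.1 CPM in the other libraries, unscaled, and late cornified envelope genes to 3.56 and 3.97 against 0.022 to 0.077 CPM. As a ratio, taste receptors (182 and 205 against 78.7 to 140 CPM) and beta defensins (13.7 and 15.5 against 3.90 to 10.7 CPM) gained less. Keratin associated protein genes (7.12 and 8.35 CPM) lay within the 3.66 to 9.04 CPM of the other libraries. Depth is argued against, since after thinning the rescue libraries had at most 703 genes at 0 and the others at least 1258. Whether genomic DNA was the whole of the gain was not settled. Silent-family genes within 50 kb of an expressed gene (137) had a higher median gain than those at least 200 kb away (244). The difference was 0.0248 CPM per kb (95% bootstrap interval 0.0134 to 0.0345), and 0.026 within olfactory receptor genes (0.0135 to 0.0386). Of the near genes 76.6% gained, against 53.3% of the far ones. DNA alone would give equal medians, but reads of overlapped expressed genes can raise the near ones, so this does not decide. DNA and run-on transcription from expressed neighbours cannot be told apart. The mean gain of the near genes was 2.77 times that of the far ones, with a bootstrap interval of 0.90 to 14.6. That interval holds 1, which by the rule set beforehand would have favoured DNA and excluded run-on, but it also holds ratios far above 1, so after it was seen the ratio was read as deciding neither. The near genes include any that overlap an expressed gene, whose own reads can then enter the gain. These gains rest on few counts, with a median olfactory receptor count of 2 in each rescue library and 0 in the others. Taste receptors, part of the silent-family set, were not silent, with median counts of 13.5 to 36 in the other libraries. The interval within olfactory receptor genes leaves them out. All the bootstrap intervals took genes as independent.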
